A study of Mus musculus with 4 samples.

How the data were processed

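Single-cell RNA-seq libraries were made from tdTomato-positive cells sorted from E15.5 mouse cerebella, 2 libraries of control embryos and 2 of En1/2 CKO embryos, each from a pool of embryos. Per the labels' protocols, cells were dissociated with Accutase, 10000 viable cells were targeted per library, 10x Genomics 3' v3.1 chemistry was used and sequencing was on a NovaSeq instrument. The authors deposited raw UMI counts per gene and cell barcode, made with Cell Ranger 6.1.0 per the file headers against mm10 with a TdTom sequence added per the labels, and with no normalisation. The other deposited files hold the cell barcodes and the gene identifiers as text, in the order of the count matrices. Whether intron reads were counted is not stated. The files held 32286 genes, and the total UMI count per library, between 5305154 and 21021428, sets the precision of each value.

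Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept. Doublets were scored per library with Scrublet, and where the automatic threshold marked under 0.5% of cells, the highest scores up to 0.8% per 1000 barcodes were removed instead. That fallback applied to both mutant libraries and to neither control, and removed 6.55% and 9.22% of their cells, against 4.3% and 1.19% in the controls. Counts were scaled to 10000 per cell and logged, and 2000 variable genes, chosen without En1, En2, sex-linked, mitochondrial, ribosomal and haemoglobin genes, gave 30 principal components, 15 neighbours and Leiden clusters at resolution 1, with no batch integration. A cluster took the name of a marker list when at least 3 of its markers, including 1 of the first 3, were raised at least 1.5-fold over the other cells (10 CPM added) and detected in at least 1% of its cells, and when no other list had more markers among the cluster's 10 leading genes, taken from genes detected in over 5% of its cells. This naming rule was settled after the clusters had been viewed and other scorings tried, and the classes are rebuilt here and are not the authors'.

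UMI counts were summed per library for all cells and for Purkinje-like, interneuron-like and progenitor-like cells. Each sum was compared between genotypes with edgeR (TMM normalisation, filterByExpr, quasi-likelihood F test, 2-sided, Benjamini-Hochberg threshold 0.05). The SE of a log2 fold change was derived from the F statistic. The difference between the Purkinje-like and interneuron-like effects was tested as an interaction with the library as a block. Shares of cells were compared with an exact permutation test of libraries, and intervals of shares are exact Clopper-Pearson 95% intervals. The floor of a share of 0 is 3 counts, and intervals and floors cover counting error only. Lists of genes, 26 in all, were tested with camera from limma at a preset correlation of 0.01, adjusted over the lists of a class. Lists, comparisons and the rule for named genes were fixed before the data were examined.

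Named genes were En1 and En2, then in each class the genes past the threshold with a mean of at least 20 CPM in either group and both mutant libraries beyond both controls, up to 10 in each direction, filled up to 10 with the smallest unadjusted p where fewer passed, and members of each list described, of which at most 2 are named. Genes named because they passed when adjusted over the list alone, clusters examined by number and genes behind counts of 5 or fewer were chosen after their values were seen. Coordinates are from the GENCODE vM21 annotation of GRCm38. Only mutants carried the floxed alleles of En1 on chromosome 1 and En2 on chromosome 5. For named genes on these chromosomes, linked DNA and the mutation cannot be told apart. They include Cntnap5a, Ecrg4, Cenpf, Btg2, Cdh7, G0s2 and Atp1b1 on chromosome 1. On chromosome 5 they include Otof, Gabra2, Cplx1, Hps4 and BC005561.

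The alternatives were RLE size factors, DESeq2, no low-count filter, a stricter cell filter (1000 genes, 5% mitochondrial), doublets kept, thinning to the smallest library, classes from control clusters, Leiden resolution 2, the replicate number as a block, each library left out, and for lists an estimated correlation and fry. Cells with at least 2000 UMIs, a crossed pairing, fits per cluster and cluster 0 alone as the interneuron side were added after the data were seen. Lists were tested only with the estimated correlation, fry, the replicate block, each library left out and cells with at least 2000 UMIs. Where leaving out a library left 1 in a group, that library was assumed to vary like the other group. The coefficient of variation, the square root of edgeR's common dispersion, was larger between controls than between mutants in each sum. Fits without a control therefore assumed a smaller spread. In data simulated at the observed dispersion trend, edgeR recovered 77.3%, 80.3%, 95.5% and 95.5% of 4-fold changes in all, Purkinje-like, interneuron-like and progenitor-like sums, and 7.4%, 11.8%, 20.6% and 23.5% of 2-fold changes. The simulation changed only genes above a minimum count and gave both genotypes the same dispersion. In the data the coefficient of variation between interneuron-like libraries was 0.338 in controls and 0.0756 in mutants. The simulated shares therefore do not give the recovery in these data.

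Tools were Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.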

Results

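Single-cell RNA-seq was performed on tdTomato-positive cells sorted from the cerebella of mouse embryos at E15.5. In these animals Ptf1a-Cre switches on the tdTomato reporter in the lineage of Ptf1a, the transcription factor that specifies cerebellar GABAergic neurons. Controls carried Cre and reporter alone, and En1/2 CKO embryos also carried homozygous floxed alleles of En1 and En2, which encode the Engrailed homeodomain transcription factors. Each genotype had 2 libraries, each from a pool of embryos whose number the labels do not give, so that p-values of edgeR and DESeq2 measure the spread between pools. Those of camera at its preset correlation compare the genes of a list with other genes. They do not measure the spread between pools. Camera with an estimated correlation rests on the few residual degrees of freedom of 2 libraries per genotype. It had little power here, so that a list that did not pass with it is not thereby shown to be unchanged. Control replicates 1 and 2 held 10991 and 4619 barcodes with 15470932 and 5305154 UMIs. En1/2 CKO replicates 1 and 2 held 8190 and 11513 barcodes with 20724086 and 21021428 UMIs. After filtering, 9955 and 1163 control cells and 4893 and 7300 mutant cells were kept.

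The libraries differed in quality within genotypes. In control replicate 2 the median mitochondrial share over all barcodes was 13.4% and 25.5% of barcodes passed the filters, against 94.6% in control replicate 1, 63.9% in En1/2 CKO replicate 1 and 69.8% in En1/2 CKO replicate 2. Kept cells had a median of 1189 and 2431 UMIs in the control libraries and 2170 and 1110 in the mutant libraries. Malat1, a nuclear non-coding RNA, stood at 85099 CPM (UMI counts scaled by the library total) in control replicate 1 and between 31463 and 33528 CPM in the other libraries. Xist, the RNA of the inactive X chromosome, stood at 944 and 2356 CPM in the control pools and at 574.5 and 1238 CPM in the mutant pools.

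The cells formed 23 clusters. Clusters 6 and 10 were Purkinje-like, with Calb1, Skor2, Foxp2 and Ebf1 raised. Clusters 0 and 5 were GABAergic interneuron-like, with Pax2, Tfap2b and Slc6a5 raised, although Neurod1 and Neurod6, genes better known from glutamatergic neurons, stood with Pax2 among the leading genes of cluster 5. Clusters 3 and 11 were Ptf1a intermediate progenitor-like and clusters 9 and 14 radial progenitor-like, and these 4 were analysed together as progenitor-like cells. Cluster 14 raised 13 of the 14 radial progenitor markers, but only Hopx of them stood among its 10 leading genes, which Aldoc led. At Leiden resolution 2 clusters that share leading genes with it (Aldoc, Mgll and Mmd2 in one, Slc14a2 and Gdpd2 in another) were named astroglia-like, and radial progenitor-like cells made up 2.929% of control and 3.599% of mutant cells on average, against 8.14% and 10.2% with the planned clusters. The remaining named clusters resembled astroglia, granule lineage, oligodendrocyte lineage, cycling cells, microglia or macrophages, choroid plexus, endothelium and mural cells. Cluster 1 (3780 cells, led by Ebf1) and clusters 4 and 17 (led by haemoglobin genes) stayed unnamed. TdTom transcripts were present at 290 to 1141 CPM in every cluster, with 475 CPM in interneuron-like cluster 0 and 775 CPM in microglia-like cluster 16.

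The targeted genes were examined first. En2 was lower in both mutant libraries than in both controls in each class tested. In interneuron-like cells En2 averaged 109 ± 16.2 CPM in controls and 25.9 ± 10.1 CPM in mutants (SD, n = 2 libraries each), a log2 fold change of -2.10 with a standard error (SE) of 0.32. The log2 fold change of En2 was -1.95 (SE 0.40) in progenitor-like cells, -0.81 (SE 0.37) in Purkinje-like cells and -1.79 (SE 0.49) over all cells. En1 differed less, with log2 fold changes of -0.26 (SE 0.34) in Purkinje-like cells, -0.48 (SE 0.33) in interneuron-like cells, -0.31 (SE 0.24) in progenitor-like cells and -0.57 (SE 0.24) over all cells. None of these values passed edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment, with adjusted p = 0.872 for En2 in interneuron-like cells, 0.754 in progenitor-like cells, 0.999 in Purkinje-like cells and 0.948 over all cells. For En1 the adjusted p was 0.877, 0.811, 0.999 and 0.948 in the same order. DESeq2 gave En2 an adjusted p of 0.0171 in interneuron-like cells and 0.0416 over all cells. Without control replicate 1 the log2 fold change of En2 was -1.96 in interneuron-like and -1.52 in progenitor-like cells. Without control replicate 2 it was -2.17 in interneuron-like cells, -2.17 in progenitor-like cells and -2.19 over all cells. En1 was at -0.89 in interneuron-like cells without control replicate 1 and at -0.77 over all cells without control replicate 2.

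En2 stood below both controls in both mutant libraries in 13 of the 16 clusters with at least 20 cells in each library, where chance separates the genotypes in this direction in 16.7% of cases. En1 did so in 7 clusters and stood above both controls in clusters 0 and 1, at 122 and 117 CPM in controls and 256 and 211 CPM in mutants in cluster 0. The 16 clusters share the same 4 libraries and are not independent draws, so that 16.7% does not measure how unusual these counts of clusters are. In microglia-like cluster 16, which should lack the gene but is among the 13, En2 was at 11.3 and 9.22 CPM in controls and 3.70 and 1.28 CPM in mutants. The values of control replicate 2 and the mutants lay under the floors of 13.8, 11.1 and 3.83 CPM that 3 counts give there. An En2 UMI was found in 14.4% and 17.5% of control and 7.41% and 3.98% of mutant interneuron-like cells, at median depths of 1253, 2351, 2032 and 1216 UMIs. In microglia-like cluster 16 it was found in 4.49% and 3.17% of control and 1.69% and 0.714% of mutant cells, at median depths of 3650, 3431, 4308 and 5587.5 UMIs. En1 lies on chromosome 1 (120602418 to 120607992) and En2 on chromosome 5 (28165694 to 28172166) in GRCm38. The labels do not say which exons the lox sites flank, so the 3' tags counted here may lie outside the deleted part and do not check the genotype.

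**Figure D1:**
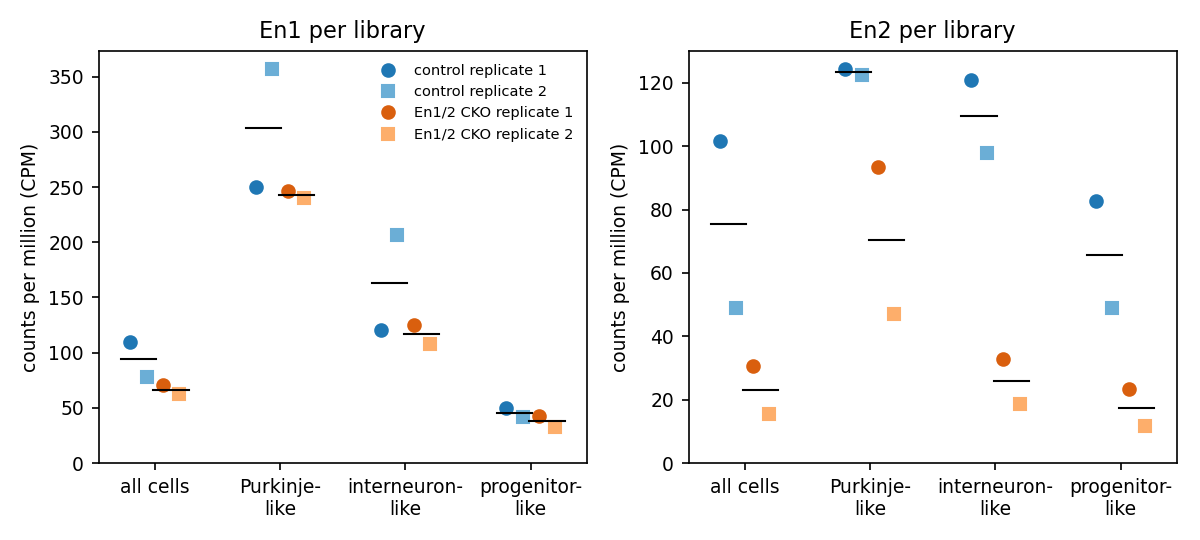
CPM of En1 and En2 (vertical axes) in all cells and in the Purkinje-like, interneuron-like and progenitor-like sums of each library, one point per library, with horizontal bars at the mean of the 2 libraries of a genotype. En2 in interneuron-like cells was 121 and 98.0 CPM in controls and 33.0 and 18.8 CPM in mutants, while En1 was 121 and 206 CPM in controls and 125 and 108 CPM in mutants.

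The series title names differentiation and survival of Purkinje cells and interneurons as the subject, and each class was compared between genotypes. In Purkinje-like cells Sncg, which encodes gamma-synuclein, and Prph, which encodes the neuronal intermediate filament peripherin, rose in both mutant libraries. Sncg averaged 3.04 ± 4.30 CPM in controls and 167 ± 45.9 CPM in mutants (SD, n = 2 each), and Prph averaged 3.04 ± 4.30 and 119 ± 4.50 CPM. Each control mean joins 6.09 CPM in control replicate 1 with 0 in control replicate 2, where 3 counts correspond to 30.6 CPM, so that the 0 sets only an upper limit. The log2 fold changes were 4.85 (SE 0.51) for Sncg and 4.37 (SE 0.48) for Prph, with an edgeR adjusted p of 0.00249 for each, and without control replicate 1 they were 9.63 (SE 1.75) and 9.15 (SE 1.94) against that 0. These transcripts came from few cells: 5 of 445 Purkinje-like cells in En1/2 CKO replicate 1 and 19 of 445 in En1/2 CKO replicate 2 carried a UMI of either gene. Those cells held 0.322 and 0.525 of the summed Purkinje marker CPM of the other Purkinje-like cells in their library. Sncg lies on chromosome 14 (34370274 to 34374789) and Prph on chromosome 15 (99055174 to 99058978) in GRCm38.

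No other gene passed in Purkinje-like cells. Among the genes with the next smallest unadjusted p-values, Cntnap5a, a contactin-associated protein, averaged 225 ± 29.8 CPM in controls and 64.1 ± 19.7 CPM in mutants (log2 fold change -1.85, SE 0.34), and Cdh9, a cadherin, 65.8 ± 20.8 and 17.9 ± 4.41 CPM (-2.06, SE 0.39). Cntnap5a lies on chromosome 1 (115684756 to 116587323), as En1 does (120602418 to 120607992), and only mutants carried the floxed alleles. An effect of the mutation and a difference in DNA linked to the floxed En1 allele cannot be told apart for Cntnap5a. Ndnf, a secreted neurotrophic factor, averaged 37.6 ± 24.3 and 7.13 ± 0.42 CPM (-2.76, SE 0.50), and S100a10, a partner of annexin A2, 2.71 ± 3.83 and 41.8 ± 9.17 CPM (3.02, SE 0.55), again with 0 under the same floor in control replicate 2. Their edgeR adjusted p-values were 0.241 for Cntnap5a, Ndnf and S100a10 and 0.245 for Cdh9, and the linker histone Hist1h1e (-2.83, SE 0.55) and the neuropeptide Sst (-1.54, SE 0.35) stood at 0.254 and 0.554. Of 8871 genes tested, edgeR called 2, both higher, and DESeq2 called the same 2, while 121 and 140 genes had an unadjusted p under 0.05 in the higher and lower direction, where chance gives 443.6. The count was 22 without the low-count filter, 1 in cells with at least 2000 UMIs, and 0 after thinning, with classes from control clusters and at Leiden resolution 2. Prph kept a log2 fold change of 4.56 (SE 1.05, adjusted p = 0.995) after thinning and 3.84 (SE 0.57, adjusted p = 0.192) in the deeper cells, with wider errors than before. The count was 289 without control replicate 1, 228 without control replicate 2, whose class held 36 cells, and 5 without En1/2 CKO replicate 2.

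Among lists fixed before the data were examined, Purkinje subtype genes lay on both sides in Purkinje-like cells. Of 28 members tested, 10 were higher and 18 lower, none passed over all genes, and 5 passed when adjusted over the list alone. These were Nrgn (115 ± 90.2 to 577 ± 339.6 CPM, log2 fold change 2.09) and Etv1 (26.4 ± 22.9 to 105 ± 13.8 CPM, 1.47) on the higher side, and Cdh9, Sst (152 ± 29.9 to 49.1 ± 16.3 CPM) and Pax6 (37.0 ± 5.43 to 11.9 ± 2.38 CPM, -1.51) on the lower side. As a group the list did not pass camera (adjusted p = 0.12, and adjusted p = 0.57 with an estimated correlation). In the Purkinje differentiation list 8 members were higher and 14 lower, Cntnap5a passed when adjusted over the list alone (0.00299), and camera gave an adjusted p of 0.056 (adjusted p = 0.57 with an estimated correlation). Nrgn is also a leading gene of cluster 6, which makes up 41.7% to 67.0% of the class in each library.

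Cell cycle genes stood lower than other genes in mutant Purkinje-like cells. All 23 members tested had a negative log2 fold change and none passed singly, over all genes or when adjusted over the list alone, with camera's adjusted p = 8.2e-08 and adjusted p = 0.57 with an estimated correlation. Cenpf, a kinetochore protein, was at 35.9 and 91.8 CPM in controls and 9.12 and 17.3 CPM in mutants. Ccnd2, a G1 cyclin, was at 195 and 71.4 CPM in controls and 60.4 and 96.6 CPM in mutants, with a log2 fold change of 0.14 without control replicate 1. Radial progenitor genes were lower (4 higher, 12 lower, camera adjusted p = 0.0021, and adjusted p = 0.57 with an estimated correlation), for example Mt3 at -0.82 and Id2 at 114 and 786 CPM in controls and 77.5 and 111 CPM in mutants. So were Notch, Shh, Wnt and Fgf signalling (1 higher, 13 lower, adjusted p = 0.0021, and adjusted p = 0.57 with an estimated correlation, for example Fgf15 at -1.28). The Ptf1a intermediate progenitor list was lower too (6 higher, 9 lower, adjusted p = 0.047, and adjusted p = 0.57 with an estimated correlation, for example Dll1 at -1.18). Cadherins and protocadherins were lower as a group (5 higher, 14 lower, adjusted p = 0.024, and adjusted p = 0.57 with an estimated correlation, with Cdh9 passing when adjusted over the list alone and Pcdh9 at 0.98). Synaptic genes were higher (28 higher, 9 lower, adjusted p = 0.0020, and adjusted p = 0.57 with an estimated correlation), for example the AMPA receptor subunit Gria3 (35.0 ± 8.30 to 74.7 ± 21.6 CPM, log2 fold change 1.28) and synapsin Syn1 (0.88), as were erythroid genes (4 of 4 higher, adjusted p = 0.021, and adjusted p = 0.57 with an estimated correlation, with Hbb-bs at 1.62 and Hbb-y at 1.59). Hbb-y was at 683 and 10.2 CPM in controls and 1792 and 578 CPM in mutants and turned to -0.42 with the stricter cell filter. Except for Cdh9, no member of these 6 lists passed over all genes or when adjusted over the list alone.

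The cell cycle call in Purkinje-like cells held with any 1 library left out. Without control replicate 1 the adjusted p was 0.062 for the signalling list, 0.52 for the intermediate progenitor list, 0.99 for cadherins and 0.53 for synaptic genes. Without control replicate 2 it was 0.29 for erythroid genes, and without En1/2 CKO replicate 1 it was 0.65 for signalling, 0.77 for radial progenitor genes, 0.40 for cadherins and 0.87, in the opposite direction, for erythroid genes. In cells with at least 2000 UMIs it was 0.051 for signalling and 0.40 for the intermediate progenitor, erythroid and synaptic lists, the last in the opposite direction. Lists were not tested with doublets kept, the stricter cell filter, thinning or other classifications. The cell cycle call was thus not checked against the doublet rule, which differed between the genotypes.

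In interneuron-like cells no gene passed, and the smallest unadjusted p-values belonged to Klhl35, a kelch-like protein, En2, and Btg2, an antiproliferative gene and p53 target. Klhl35 averaged 147 ± 8.77 CPM in controls and 453 ± 37.6 CPM in mutants (log2 fold change 1.60, SE 0.24), and Btg2 58.9 ± 14.0 and 175 ± 5.00 CPM (1.51, SE 0.24). The transcription factor Bcl11b (23.9 ± 7.83 to 82.0 ± 7.61 CPM, log2 fold change 1.65, SE 0.27) and the phosphatase Dusp26 (38.7 ± 5.69 to 107 ± 18.3 CPM, 1.41, SE 0.25) were also higher in both mutant libraries. Gabra2, the alpha2 subunit of the GABA-A receptor, averaged 38.7 ± 5.69 and 13.5 ± 1.96 CPM (log2 fold change -1.57, SE 0.26). Tmem179 (-1.63, SE 0.27), the neural protein Pianp (-1.93, SE 0.36) and the secreted synaptic protein C1ql3 (-2.62, SE 0.48) were lower. Each of these genes had an edgeR adjusted p of 0.872. Btg2 lies on chromosome 1 (134075170 to 134079120), as En1 does (120602418 to 120607992). Gabra2 lies on chromosome 5 (70957597 to 71095849), as En2 does (28165694 to 28172166). Linked DNA and the mutation cannot be told apart for either gene.

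Of 10841 genes tested in interneuron-like cells, edgeR called 0, with 249 higher and 348 lower at an unadjusted p under 0.05, where chance gives 542. DESeq2 called 3, Klhl35 (log2 fold change 1.61), Gm10076 (2.29) and En2 (-2.09), and edgeR called 52 without the low-count filter. Gm10076 is a predicted gene named after its values were seen, and reads may be shared with similar copies. The count was 975 without control replicate 1 and 2789 without control replicate 2. Both of these fits took the spread between libraries from the mutants alone. The coefficient of variation was 0.0756 between the mutants and 0.338 between the controls, so that these counts are not comparable with the others. Different clusters held most of the interneuron-like class in different libraries: cluster 0 held 96.3% and 18.4% of it in the controls and 46.2% and 62.4% in the mutants.

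Cadherins and protocadherins and cell cycle genes stood lower than other genes in mutant interneuron-like cells. All 14 cadherins and protocadherins tested had a negative log2 fold change (camera adjusted p = 4.6e-06, and adjusted p = 0.56 with an estimated correlation), for example Cdh7 (44.2 ± 19.3 to 21.6 ± 2.88 CPM, log2 fold change -1.16) and Pcdh11x (-1.41). Cdh7 lies on chromosome 1 (109982431 to 110140157), as En1 does, so that linked DNA and the mutation cannot be told apart for it. Of 29 cell cycle genes, 26 were lower and 3 higher (adjusted p = 2.4e-06, and adjusted p = 0.62 with an estimated correlation), for example the mitotic kinase Plk1 (-2.74) and the G1 cyclin Ccnd1 (26.5 ± 5.68 to 15.01 ± 2.00 CPM, -0.92). Radial progenitor genes (5 higher, 16 lower, adjusted p = 0.039, for example Mt1 and Slc1a3 at -1.37 and -1.08) and the signalling list (4 higher, 20 lower, adjusted p = 0.039, for example Jag2 and the Shh receptor Ptch1 at -1.28 and -0.80) were also lower, with adjusted p = 0.76 and adjusted p = 0.62 with an estimated correlation. No member of these 4 lists passed over all genes or when adjusted over the list alone.

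Genes of the p53 and apoptosis list and of the immediate early and dissociation stress list stood higher in mutant interneuron-like cells. In the first, 15 of 21 were higher and 6 lower (adjusted p = 0.0065, and adjusted p = 0.56 with an estimated correlation), including the BH3-only gene Bbc3 (29.9 ± 3.93 to 47.4 ± 1.05 CPM, log2 fold change 0.71). In the second, 9 of 12 were higher and 3 lower (adjusted p = 0.0034, and adjusted p = 0.56 with an estimated correlation), including Fos (6.17 ± 2.83 to 12.15 ± 1.62 CPM, 1.32). Btg2, a member of both lists, was the only gene of either to pass when adjusted over the list alone, and none passed over all genes. Btg2 also belongs to the Ptf1a intermediate progenitor list and passed edgeR when adjusted over that list alone (0.0111). Since Btg2 shares chromosome 1 with En1, linked DNA and the mutation cannot be told apart for it, and it does not stand for these lists. Posterior hindbrain genes were higher too (6 of 7, adjusted p = 0.0021, and adjusted p = 0.56 with an estimated correlation, none past over all genes or when adjusted over the list alone), for example Hoxb2 (2.98 ± 1.32 to 9.16 ± 1.97 CPM, log2 fold change 1.33). Hoxa3 (1.95) was at 1.56 and 12.2 CPM in controls and 8.74 and 16.4 CPM in mutants and turned to -0.06 without control replicate 1. At Leiden resolution 2 a posterior hindbrain-like cluster of 46 cells held 3 and 1 control and 24 and 18 mutant cells, 0.058 ± 0.04% and 0.368 ± 0.172% of all kept cells (SD, n = 2, exact permutation p = 0.333). Synaptic genes did not pass (10 higher, 27 lower, adjusted p = 0.060, and adjusted p = 0.56 with an estimated correlation), and Gabra2 passed when adjusted over the list alone (0.0303).

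Without control replicate 1 none of these 7 calls in interneuron-like cells held, with adjusted p = 0.49 for cadherins, 0.71 for cell cycle genes, 0.95 for radial progenitor genes, 0.11 for signalling, 0.49 for the p53 list and the immediate early list and 0.98 for posterior hindbrain genes. There the radial progenitor and posterior hindbrain lists changed direction. Without control replicate 2 the signalling list was at 0.089, and without En1/2 CKO replicate 1 cell cycle genes were at 0.079, signalling at 0.58 and radial progenitor genes at 0.78 in the opposite direction. In cells with at least 2000 UMIs signalling was at 0.17 and radial progenitor genes at 0.063.

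In progenitor-like cells no gene passed either. G0s2, an inhibitor of triglyceride lipase, had the smallest unadjusted p, with 23.6 ± 1.19 CPM in controls and 4.28 ± 0.32 CPM in mutants (log2 fold change -2.46, SE 0.31). Atp1b1, a subunit of the sodium-potassium pump, averaged 96.45 ± 7.84 and 37.8 ± 2.29 CPM (-1.39, SE 0.20), and Tmem14c, a mitochondrial membrane protein, 139 ± 25.7 and 49.4 ± 9.01 CPM (-1.53, SE 0.23). Anxa2, a calcium-dependent phospholipid-binding protein, was higher in mutants, with 22.2 ± 3.14 and 77.03 ± 7.76 CPM (1.79, SE 0.26). Cd27 (-2.55, SE 0.43), Hps4 (-1.23, SE 0.22) and BC005561 (-1.10, SE 0.20) were lower, and each of these 7 genes had an edgeR adjusted p of 0.754. G0s2 and Atp1b1 lie on chromosome 1, as En1 does, and Hps4 and BC005561 on chromosome 5, as En2 does. Linked DNA and the mutation cannot be told apart for them, though they lie farther from the targeted genes than Cntnap5a and Otof do.

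Of 11457 genes tested in progenitor-like cells, edgeR called 0, with 287 higher and 408 lower at an unadjusted p under 0.05, where chance gives 573. DESeq2 called 1, Gm10076 (log2 fold change 2.58), and edgeR called 94 without the low-count filter. The count was 1461 without control replicate 1, 1947 without control replicate 2 and 2 without En1/2 CKO replicate 2. Fits without a control took the spread between libraries from the mutants alone, where the coefficient of variation was 0.0785, against 0.326 between controls. Cluster 3 held 72.2% of the progenitor-like cells of control replicate 1 and 29.4% to 34.0% of those of the other libraries.

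Synaptic genes were lower as a group in mutant progenitor-like cells (7 higher, 26 lower, camera adjusted p = 0.0096, and adjusted p = 0.61 with an estimated correlation), for example Gabra2 (41.0 ± 1.48 to 21.9 ± 0.17 CPM, log2 fold change -0.93) and the complexin Cplx1 (-1.83). Purkinje subtype genes were lower (6 higher, 20 lower, adjusted p = 0.042, and adjusted p = 0.61 with an estimated correlation), among them Ebf1, an early B-cell factor of developing Purkinje cells (1100.3 ± 27.0 to 549.6 ± 30.3 CPM, -1.04), and Rorb (-1.37). Radial progenitor genes were higher (12 higher, 9 lower, adjusted p = 0.042, and adjusted p = 0.62 with an estimated correlation), for example the Notch effectors Hes1 (61.8 ± 22.0 to 118 ± 10.1 CPM, 0.92) and Hes5 (0.48). Cell cycle genes (9 higher, 18 lower, adjusted p = 0.047, and adjusted p = 0.61 with an estimated correlation, for example Nusap1 and Ccna2 at -1.23 and -1.02) and cadherins and protocadherins (2 higher, 16 lower, adjusted p = 0.047, and adjusted p = 0.61 with an estimated correlation, for example Pcdh11x and Pcdh19 at -1.43 and -1.19) were lower. No member of these 5 lists passed over all genes or when adjusted over the list alone.

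In progenitor-like cells radial progenitor genes turned lower without control replicate 1 (adjusted p = 0.0045). Cell cycle genes were at 0.18, 0.12 and 0.11 without control replicate 1, control replicate 2 and En1/2 CKO replicate 1. Cadherins were at 0.48, 0.062 and 0.081 without control replicate 2, En1/2 CKO replicate 1 and En1/2 CKO replicate 2, and synaptic genes at 0.056 without control replicate 2. In cells with at least 2000 UMIs Purkinje subtype genes were at 0.35 and radial progenitor genes at 0.85.

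Whether the effect of genotype differed between Purkinje-like and interneuron-like cells was tested within libraries. Relative to interneuron-like cells, the effect in Purkinje-like cells was more positive for Olfm1, an olfactomedin-family secreted protein (log2 difference 1.76, SE 0.21, edgeR adjusted p = 8.7e-05), for the axon guidance receptor Robo2 (1.89, SE 0.30, 0.00422), for Gabra2 (2.05, SE 0.37, 0.00948) and for Nrgn, a calmodulin-binding protein (1.71, SE 0.30, 0.00894). It was more negative for Klhl35 (-1.92, SE 0.29, 0.00154), Sst (-1.54, SE 0.26, 0.00534) and Pax2 (-1.36, SE 0.24, 0.00898), which is also a marker by which interneuron-like clusters were named. Robo2 was at 237 and 235 CPM in control and 246 and 217 CPM in mutant Purkinje-like cells, against 42.5 and 22.5 CPM in control and 14.2 and 6.26 CPM in mutant interneuron-like cells. En2 was lower by less in Purkinje-like cells (log2 difference 1.37, SE 0.26, adjusted p = 0.0125), and En1 gave 0.11 (SE 0.21, adjusted p = 0.937).

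Of 10302 genes tested for this difference, 38 passed, 27 more positive and 11 more negative in Purkinje-like cells, and 923 had an unadjusted p under 0.05 where chance gives 515. The count was 0 without control replicate 1 or after thinning, 68 without control replicate 2, 7 without En1/2 CKO replicate 1, 18 without En1/2 CKO replicate 2 and 86 without the low-count filter. Without control replicate 1 the difference was larger than with all libraries for Olfm1 (1.98, SE 0.32), Gabra2 (2.42, SE 0.93), Nrgn (2.89, SE 0.93) and Sst (-2.13, SE 0.45) and smaller for Robo2 (1.19, SE 0.66), Klhl35 (-1.72, SE 0.75), Pax2 (-1.11, SE 0.36) and En2 (1.23, SE 0.45), with wider errors for each. Against cluster 0 alone, an alternative added after the data were seen, Robo2 (1.04, adjusted p = 0.195), Gabra2 (1.28, 0.167) and Klhl35 (-0.94, 0.121) did not pass, while Olfm1 (1.46), Nrgn (1.53), Sst (-2.25) and Pax2 (-1.05) did. Cluster 0 held 96.3% and 18.4% of the interneuron-like cells of the control libraries. Against it the En2 difference was 0.88 (SE 0.32, adjusted p = 0.232) and the En1 difference was -0.99 (SE 0.24, adjusted p = 0.0124), while against cluster 5 the En1 difference was 0.63 (SE 0.29).

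**Figure D2:**
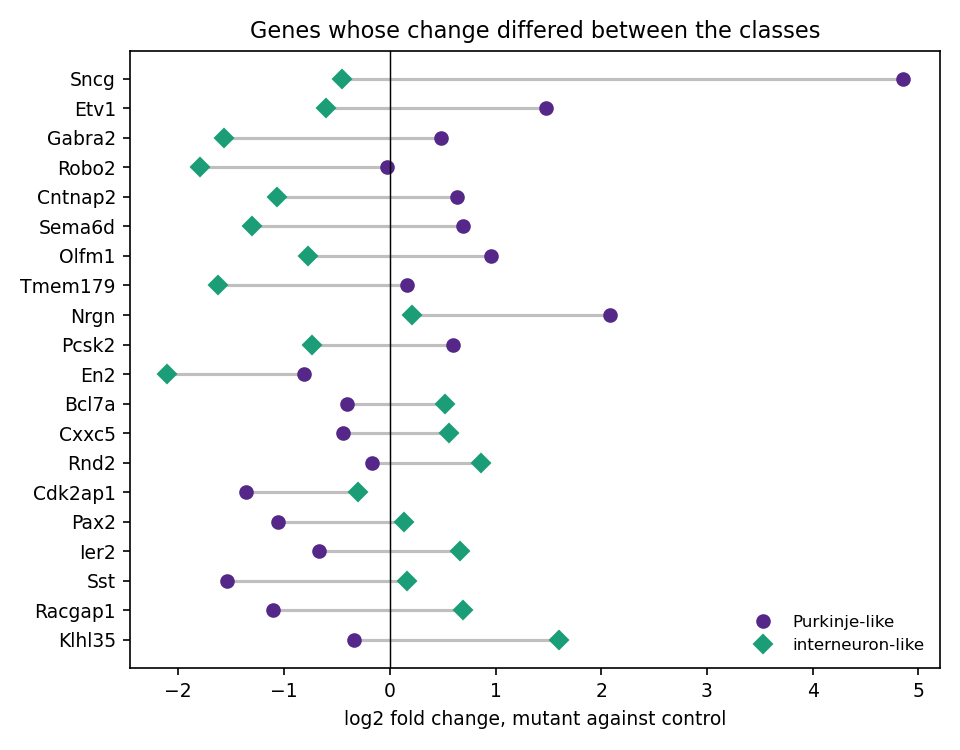
Log2 fold change, mutant over control, of named genes in Purkinje-like and in interneuron-like cells, for genes whose difference between the classes passed the test. Gabra2 stood at 0.48 in Purkinje-like and -1.57 in interneuron-like cells, and Klhl35 at -0.34 and 1.60.

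The shares of the 3 classes among kept cells overlapped between genotypes with the planned filters and clusters. Purkinje-like cells made up 6.70 ± 5.09% of control and 7.60 ± 2.12% of mutant cells (SD, n = 2; exact permutation test, 2-sided, p = 1.0), interneuron-like cells 23.1 ± 6.84% and 18.3 ± 4.50% (exact permutation p = 0.667) and progenitor-like cells 18.0 ± 12.2% and 22.5 ± 8.19% (exact permutation p = 0.667). With 2 libraries against 2, the smallest p this test allows is 0.333. Purkinje-like cells were 10.3% (exact Clopper-Pearson 95% interval 9.71 to 10.9) and 3.10% (2.18 to 4.26) of the control libraries and 9.10% (8.30 to 9.94) and 6.096% (5.56 to 6.67) of the mutant libraries. Interneuron-like cells were 27.9% (27.0 to 28.8) and 18.2% (16.05 to 20.6) of the control libraries and 21.5% (20.4 to 22.7) and 15.1% (14.3 to 15.98) of the mutant libraries. Progenitor-like cells were 9.34% (8.78 to 9.93) and 26.7% (24.1 to 29.3) of the control libraries and 28.3% (27.1 to 29.6) and 16.7% (15.9 to 17.6) of the mutant libraries. The intervals cover counting error only, and the tdTomato sort, the share of barcodes that passed the filters and depth can each set these shares. edgeR on the cell counts gave an adjusted p of 0.939 for each class.

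The Purkinje-like difference of 0.90 percentage points was -2.70 without control replicate 2, 4.50 without control replicate 1, -0.60 without En1/2 CKO replicate 1 and 2.40 without En1/2 CKO replicate 2, and -2.35 in cells with at least 2000 UMIs and -3.63 with the stricter cell filter. In cells with at least 2000 UMIs progenitor-like shares did not overlap, at 21.1 ± 7.59% in controls and 39.3 ± 3.30% in mutants (SD, n = 2, exact permutation p = 0.333), and the stricter filter gave a difference of 15.1. With classes from control clusters interneuron-like shares did not overlap, at 32.2 ± 8.51% and 22.8 ± 3.48% (SD, n = 2, exact permutation p = 0.333). The interneuron-like difference of -4.75 was 0.09 without control replicate 1, -9.59 without control replicate 2, -7.93 without En1/2 CKO replicate 1 and -1.57 without En1/2 CKO replicate 2, and the progenitor-like difference of 4.54 was -4.12, 13.2, -1.26 and 10.3 in the same order.

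**Figure D3:**
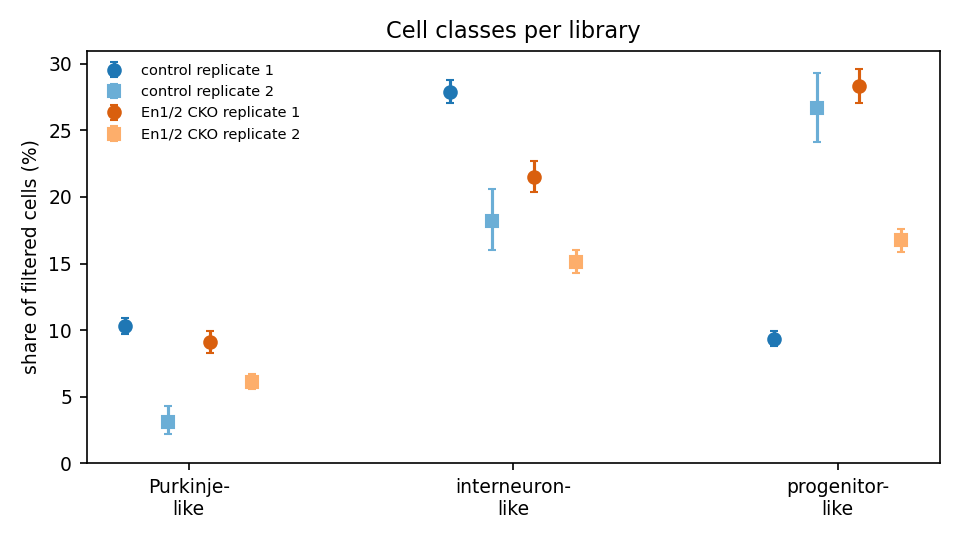
Share of kept cells (percent, vertical axis) in the Purkinje-like, interneuron-like and progenitor-like classes, one point per library with exact 95% binomial intervals. The 2 control libraries lay apart by as much as the genotypes did, at 10.3% and 3.10% for Purkinje-like and 9.34% and 26.7% for progenitor-like cells.

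Choroid plexus-like cells were found in both mutant libraries and in neither control. They numbered 66 of 4893 cells in En1/2 CKO replicate 1 and 93 of 7300 in En1/2 CKO replicate 2, a mean share of 1.31 ± 0.053% (SD, n = 2). That SD joins different clusters: cluster 19 (median 10408 UMIs) held the 66 cells and 23 of the 93, or 1.35% and 0.315% of the mutant libraries, and the other 70 formed cluster 21 (median 989 UMIs), which had no cell from any other library. The controls held 0 of 9955 and 0 of 1163 cells, which allows shares of up to 0.03% and 0.258%. The exact permutation p was 0.333, the smallest possible, and edgeR on cell counts gave an adjusted p of 0.0139. With classes from control clusters, a choroid plexus-like cluster whose leading genes also include vascular markers held 29 and 6 control cells and 65 and 53 mutant cells, 0.403% and 1.03% on average. The planned clusters named 22 and 6 control cells mural or meningeal and 7 and 0 endothelial, names that the control clusters lacked. The control cells of that cluster may thus be vascular and do not show choroid plexus in controls. Over all cells Ttr and Kcne2 had the smallest unadjusted p-values. Ttr, the thyroid hormone carrier transthyretin, averaged 8.87 ± 5.83 CPM in controls and 8637 ± 5939.8 CPM in mutants (log2 fold change 9.78, SE 0.97), and the potassium channel subunit Kcne2 0.04 ± 0.05 and 31.1 ± 20.3 CPM. Ecrg4 (3.79, SE 0.44), Otof (0.11 ± 0.15 to 6.71 ± 1.71 CPM), Anxa2 (20.4 ± 1.51 to 63.7 ± 3.63 CPM, 1.57, SE 0.20), the folate receptor Folr1 (0.37 ± 0.43 to 35.96 ± 22.4 CPM), Htr2c (5.73, SE 0.82), Clu (2.27, SE 0.33), Krt18 (0.07 ± 0.10 to 12.8 ± 8.71 CPM) and Calml4 (3.33, SE 0.51) followed. Each of these genes had an edgeR adjusted p of 0.948, and no fold change is given for Kcne2, Otof, Folr1 and Krt18, which had at most 3 UMIs over the control libraries. Otof also passed in a fit of astroglia-like cluster 2 (edgeR adjusted p = 0.000369). It stood there at 0.81 and 0 CPM in controls, the 0 under a floor of 105 CPM, and 45.2 and 28.9 CPM in mutants. Otof lies on chromosome 5 (30367062 to 30461932), as En2 does, so that linked DNA and the mutation cannot be told apart for it. All 4 choroid plexus or ciliated genes tested were higher and passed when adjusted over the list alone, none over all genes, with camera's adjusted p = 1.4e-07 and adjusted p = 0.49 with an estimated correlation.

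**Figure D4:**
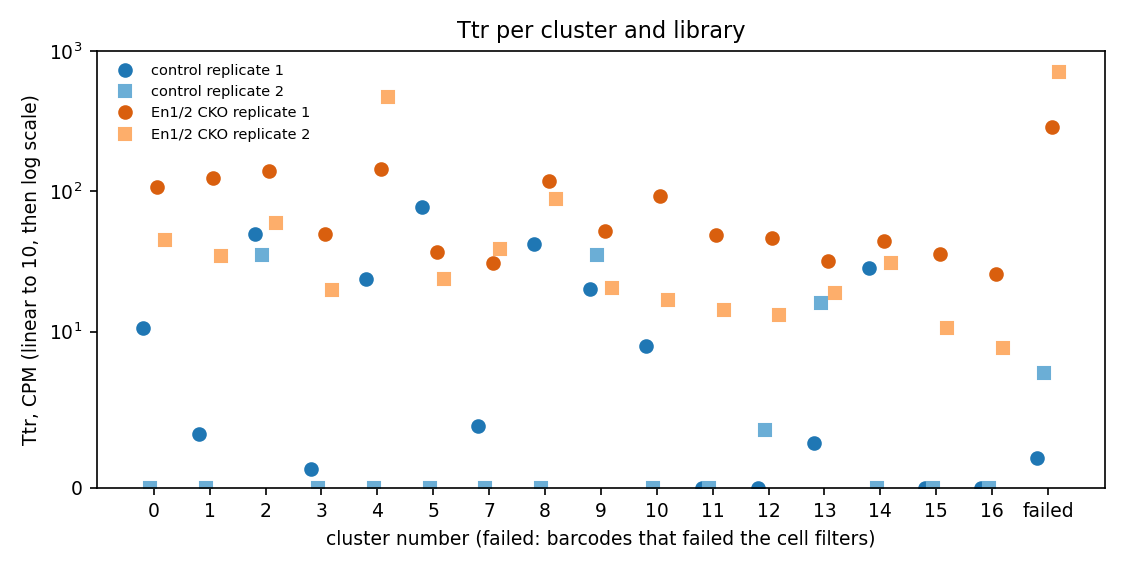
Ttr CPM (vertical axis, linear to 10 and logarithmic above) per library in each cluster with at least 20 cells in every library and in barcodes that failed the filters, one point per library. Microglia-like cluster 16 held 0 CPM in both controls and 25.9 and 8.94 CPM in mutants, and failed barcodes 1.91 and 7.36 CPM in controls and 286.4 and 711.2 CPM in mutants.

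Lists of synaptic, Purkinje and interneuron genes stood lower and the radial progenitor list higher over all mutant cells by camera at its preset correlation, and none passed with an estimated correlation. The sum over all cells includes the mix of cell types, and several of these lists hold the markers by which clusters were named. A different mix and a change within cells cannot be told apart here. Within Purkinje-like cells 8 Purkinje differentiation genes were higher and 14 lower. The axon guidance list (13 higher, 28 lower, camera adjusted p = 0.061) and the Ptf1a intermediate progenitor list (13 higher, 7 lower, 0.11) did not pass. Synaptic genes (3 higher, 36 lower, camera adjusted p = 7.5e-06, and adjusted p = 0.49 with an estimated correlation, for example Gabra2 at -0.89) were lower. So were Purkinje differentiation genes (1 higher, 23 lower, adjusted p = 0.00015, and adjusted p = 0.49 with an estimated correlation, for example Cntnap5a and Pcp2 at -2.10 and -2.22) and Purkinje subtype genes (5 higher, 24 lower, adjusted p = 0.0018, and adjusted p = 0.49 with an estimated correlation, for example Ebf1 at 1281 ± 72.1 and 591 ± 32.9 CPM). Cadherins and protocadherins (2 higher, 21 lower, adjusted p = 0.00083, and adjusted p = 0.49 with an estimated correlation, for example Cdh7 and Cdh9 at -0.98 and -2.40) and GABAergic interneuron genes (3 higher, 16 lower, adjusted p = 0.0072, and adjusted p = 0.49 with an estimated correlation, for example Npy and Tfap2a at -1.43 and -0.45) were lower. Radial progenitor genes (16 higher, 5 lower, adjusted p = 0.00025, and adjusted p = 0.49 with an estimated correlation, with Hes1 at 34.0 ± 4.74 and 76.2 ± 4.59 CPM and Hes5 at 0.78) and cell cycle genes (18 higher, 12 lower, adjusted p = 0.0013, and adjusted p = 0.61 with an estimated correlation, for example Mki67 and Aurkb at 0.44 and 0.75) were higher. Notch, Shh, Wnt and Fgf signalling (22 higher, 15 lower, adjusted p = 0.0087, and adjusted p = 0.51 with an estimated correlation), posterior hindbrain genes (8 higher, 1 lower, adjusted p = 0.0087, and adjusted p = 0.56 with an estimated correlation, for example Hoxb2 at 1.27) and the p53 and apoptosis list (19 higher, 9 lower, adjusted p = 0.042, and adjusted p = 0.49 with an estimated correlation, for example Perp and Btg2 at 2.57 and 1.26) were higher. The posterior hindbrain-like cluster seen at Leiden resolution 2 held 3 and 1 control and 24 and 18 mutant cells. No member of these 10 lists passed over all genes or when adjusted over the list alone.

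Of 14833 genes tested over all cells, edgeR called 0, with 442 higher and 257 lower at an unadjusted p under 0.05, where chance gives 741.7, and DESeq2 called 45 higher and 8 lower. The count was 375 without control replicate 1, 1716 without control replicate 2, 5 without En1/2 CKO replicate 1 (Ttr, Kcne2, Folr1, Clic6 and 2900040C04Rik) and 39 without En1/2 CKO replicate 2. Without control replicate 1 none of the 11 list calls over all cells held: cell cycle genes turned lower (adjusted p = 0.0012), and the others lay between 0.11 for the choroid plexus list and 0.99 for Purkinje differentiation genes, with that list, signalling and posterior hindbrain genes changing direction. Without En1/2 CKO replicate 1 the p53 list was at 0.084, and without En1/2 CKO replicate 2 it was at 0.060, signalling at 0.085 and posterior hindbrain genes at 0.12. In cells with at least 2000 UMIs cell cycle genes were at 0.49, signalling at 0.27, interneuron genes at 0.18, posterior hindbrain genes at 0.097 and the p53 list at 0.068.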

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

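All tests that weigh explanations here were chosen after the results were seen, while the test of the difference between classes was planned. Sncg and Prph were higher in mutant Purkinje-like cells, and the effect on Sncg also differed from that in interneuron-like cells by 5.45. Free RNA in the droplets is argued against, since Sncg in interneuron-like cells reached at most 0.0216 of its level in Purkinje-like cells of the mutant libraries. The 5 and 19 mutant cells with a Sncg or Prph UMI held at most 0.525 of the Purkinje marker level of the others, with medians of 2614 and 4184 UMIs against 1338.5 and 1126, Ebf1 at 829 and 948.8 CPM against 1452.4 and 1517.1, Foxp2 at 55.3 and 135.5 CPM against 804.6 and 684.2, Slc17a6, a glutamate transporter, at 82.9 and 123.2 against at most 30.3, and Isl1 at 386.8 and 98.6 against 0. At Leiden resolution 2, 4 and 11 of them left the Purkinje-like class, Sncg was among the leading genes of a glutamatergic neuron-like cluster there and in the control clusters but also of astroglia-like cluster 21 there and of radial progenitor-like cluster 14, and 0 genes passed with either classification, where both fell under the low-count filter. Prph was the first leading gene of that cluster among the control clusters. In Purkinje-like cells as a whole Slc17a6 (4.40 ± 6.22 to 30.6 ± 12.7 CPM) and Lhx9 (3.04 ± 4.30 to 18.3 ± 3.12 CPM) stood higher in mutants. Both passed edgeR when adjusted over the granule and glutamatergic list alone, as Pax6 and Mfap4 did on the lower side. Cells of another type and Purkinje cells with these transcripts cannot be told apart from so few cells, some of which kept the class. The difference between genotypes passed edgeR, but which of these cells underlie it was not tested.

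En2 was lower by less in Purkinje-like than in interneuron-like cells (1.37). Free En2 RNA is argued against by a level in Purkinje-like cells 25.25 and 36.85 times that in microglia-like cells of En1/2 CKO replicates 1 and 2, where the latter rest on 1 UMI each and the exact 95% intervals of the ratios start at 4.41 and 6.23. Unequal makeup of the interneuron-like class is argued against as the whole cause, though it may account for part, by differences of 0.882 (SE 0.319) against cluster 0 alone and 1.263 (SE 0.375) against cluster 5 alone, whose normal 95% intervals lie above 0; neither passed (adjusted p = 0.232 and 0.310, against 0.0125 for the 1.37, SE 0.26, of the whole class), with smaller differences and wider errors. Depth stays open: Purkinje-like cells and cluster 0 had medians of 2639.5 and 1005 UMIs in control replicate 2, and without that library, where the depths lie within 1.3 times, the difference was 0.892 (SE 0.290, adjusted p = 0.0778) but rests on 1 control. The makeup of the Purkinje-like class differed too, with cluster 6 at 41.7% to 67.0% of it. En2 averaged 213 ± 51.2 CPM in control and 102 ± 21.6 CPM in mutant cells of cluster 6. Its log2 fold change was -1.13 (SE 0.54) in cluster 10, against -0.81 for the class. For cluster 6 alone against cluster 0 the difference was 0.876 (SE 0.342, edgeR adjusted p = 0.450), with 15 cluster 6 cells in control replicate 2. A difference in how the alleles recombined or in how En2 is regulated stays open and was not tested.

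Ttr was detected in barcodes that failed the filters at 286.4 CPM in En1/2 CKO replicate 1 and 711.2 CPM in En1/2 CKO replicate 2, above the 1.91 and 7.36 CPM of the controls. Free choroid plexus RNA may raise Ttr outside the choroid plexus-like cells, since both mutant libraries stood above both controls in 14 of 16 clusters, microglia-like cells among them. Whether choroid plexus cells were collected without the reporter remains open: their TdTom level was at least 1.072 times that of interneuron-like cells in the mutant libraries, but microglia-like cells, outside the Ptf1a lineage, gave 0.909, so that TdTom RNA does not separate the lineage here. More choroid plexus tissue in the mutant dissections and an effect of genotype cannot be told apart with 2 pools each.

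The effect of genotype also differed between Purkinje-like and interneuron-like cells, by the interaction test, for the following genes. The log2 difference was 2.12 for Etv1, 2.05 for Gabra2, 1.89 for Robo2, 1.87 for Cntnap2, 1.77 for Sema6d, 1.76 for Olfm1, 1.74 for Tmem179, 1.71 for Nrgn and 1.48 for Pcsk2. It was -1.92 for Klhl35, -1.85 for Racgap1, -1.54 for Sst, -1.42 for Ier2, -1.36 for Pax2, -1.23 for Cdk2ap1, -1.18 for Rnd2, -1.01 for Cxxc5 and -0.99 for Bcl7a. Against cluster 0 alone 5 of the 20 genes named for this test (Sncg, Olfm1, Nrgn, Sst and Pax2) still passed, 13 no longer passed and 2 turned, and without control replicate 1 none of the 20 passed. There the difference was larger than with all libraries for Sncg (5.86), Sema6d (3.42), Tmem179 (2.91), Nrgn (2.89), Etv1 (2.83), Gabra2 (2.42), Olfm1 (1.98), Pcsk2 (1.70) and Sst (-2.13), with wider errors for those with an SE, for example 0.93 against 0.37 for Gabra2. Against cluster 0 the difference was 1.52 (SE 0.51) for Cntnap2, 1.495 (SE 0.49) for Sema6d and -0.97 (SE 0.34) for Ier2, which no longer passed with SEs of 0.40, 0.39 and 0.30 before, and it was 0.83 for Etv1, 1.28 for Gabra2, 1.04 for Robo2, 0.99 for Tmem179, 0.57 for Pcsk2, -0.94 for Klhl35, -0.82 for Racgap1, -0.08 for Cdk2ap1 and -0.61 for Bcl7a. For En1 the difference was -0.99 against cluster 0 alone and 0.63 (SE 0.29, not past the threshold) against cluster 5, the other interneuron-like cluster.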

How the results depend on the processing

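The deep-cell, crossed-pairing and cluster 0 alternatives were chosen after the data were seen. RLE size factors left every count of genes within 1.5 times, with 38 genes for the difference between classes, as did the stricter cell filter and kept doublets for the counts within classes. DESeq2 called 53 genes in all cells, 3 in interneuron-like and 1 in progenitor-like cells. Without the low-count filter 22, 52 and 94 genes passed in Purkinje-like, interneuron-like and progenitor-like cells and 86 for the difference between classes. In Purkinje-like cells 0 genes passed after thinning, with classes from control clusters and at Leiden resolution 2, against 2 with edgeR and DESeq2 and 261 at an unadjusted p under 0.05, and 1 passed in cells with at least 2000 UMIs. Prph there was at 4.56 (SE 1.05) after thinning, 3.84 (SE 0.57) in cells with at least 2000 UMIs and 4.46 (SE 0.59) with crossed pairing, none past the threshold, against 4.37 (SE 0.48), so that these calls ended with wider errors and folds of similar size, while Sncg after thinning, and both genes with the other classifications, fell under the low-count filter. Without control replicate 1 Sncg and Prph were at 9.63 (SE 1.75) and 9.15 (SE 1.94). For the difference between classes 0 passed after thinning. With 1 library left out, counts ran from 5 to 1716 in all cells, 3 to 289 in Purkinje-like, 0 to 2789 in interneuron-like and 0 to 1947 in progenitor-like cells, and 0 to 68 for the difference between classes. Fits within a class without a control took the spread between libraries from the mutants alone. Its coefficient of variation was 0.1255, 0.132, 0.0756 and 0.0785 in all, Purkinje-like, interneuron-like and progenitor-like cells. Between controls it was 0.378, 0.3555, 0.338 and 0.326 in the same order, so that counts without a control are not comparable with the others. Other causes were not tested.

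The labels do not say that the numbers pair the libraries, and same-numbered deviations correlated across genes at 0.051 in all cells, 0.047 in Purkinje-like, -0.17 in interneuron-like and -0.10 in progenitor-like cells. With a replicate block 90, 12, 7 and 10 genes passed in all, Purkinje-like, interneuron-like and progenitor-like cells, and 13, 12, 11 and 10 lists. The block gave En2 log2 fold changes of -1.77 in all, -2.12 in interneuron-like and -1.96 in progenitor-like cells, each past the threshold. A crossed pairing gave 2 genes in all cells (Folr1 and Kcne2), 1 in Purkinje-like (Sncg), 0 in interneuron-like and 1 in progenitor-like cells (Gm10076).

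The Purkinje-like share turned to -3.63 with the stricter filter, -0.17 with classes from control clusters and -2.35 in cells with at least 2000 UMIs. With 1 library left out the differences ran from -2.70 to 4.50 for Purkinje-like, -9.59 to 0.09 for interneuron-like and -4.12 to 13.19 for progenitor-like shares. They were -2.70 without control replicate 2 and -0.60 without En1/2 CKO replicate 1 for Purkinje-like cells, and -4.12 without control replicate 1 and -1.26 without En1/2 CKO replicate 1 for progenitor-like cells. The cause was not tested.

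With an estimated correlation 0 lists passed in all, Purkinje-like, interneuron-like and progenitor-like cells, and with fry 0 in each, against 11, 7, 7 and 5 with camera's preset correlation, and 3 passed in progenitor-like cells with at least 2000 UMIs. The estimated correlation and fry rest on the few residual degrees of freedom of these libraries and had little power. Their counts of 0 therefore do not separate correlated genes from a lack of power. With 1 library left out 3 to 16, 4 to 10, 2 to 13 and 4 to 11 lists passed in these classes. The cause was not tested.

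En2 passed with DESeq2 in all cells (-1.78) and interneuron-like cells (-2.09), and without the low-count filter in interneuron-like (-2.07) and progenitor-like cells (-1.91). En1 turned to 0.16 in Purkinje-like cells with classes from control clusters and to 0.03 in interneuron-like cells at Leiden resolution 2. With 1 library left out En1 ran from -0.77 to -0.33 in all, -0.54 to -0.05 in Purkinje-like, -0.89 to -0.02 in interneuron-like and -0.49 to -0.14 in progenitor-like cells, and En2 from -2.36 to -1.19, -1.39 to -0.39, -2.57 to -1.75 and -2.52 to -1.52. The cause was not tested.

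Of the values of named genes under alternatives other than left-out libraries, 810 kept direction and side of the threshold, 61 passed newly, 28 no longer passed and 6 turned. Left-out libraries gave 252, 111, 53 and 3. Hbb-y in Purkinje-like cells turned to -0.42 with the stricter filter, and without control replicate 1 Ccnd2 in Purkinje-like cells to 0.14 and Hoxa3 in interneuron-like cells to -0.06. With 1 library left out the value for Ccnd2, Purkinje-like cells, ran from -1.33 to 0.14 and Hoxa3 from -0.06 to 2.98. Between classes Ier2 turned to 0.66 and En1 to -1.49 after thinning, Rnd2 to 0.36, Cxxc5 to 0.03 and En1 to -0.99 against cluster 0 alone, and En1 ran from -0.07 without control replicate 2 to 0.38 without control replicate 1. The cause was not tested. Control replicate 2 held 36 Purkinje-like cells with 97993 UMIs.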

Other observations

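The fits by cluster described here were chosen after the data were seen, and the genes were named after their values were seen. In astroglia-like cluster 2, Cwc22, a splicing factor, stood at 44.6 and 0 CPM in controls and 388 and 194 CPM in mutants (log2 fold change 2.79, edgeR adjusted p = 4.7e-05). Control replicate 2 held 32 cells and 28468 UMIs there, so that 3 counts correspond to 105 CPM and its value of 0 for Cwc22 lies under that floor. Nrxn3, a presynaptic neurexin, fell from 156 and 281 CPM to 43.1 and 27.5 CPM (-2.19, edgeR adjusted p = 0.000193). In cluster 1 the smallest adjusted p belonged to Ttr (4.31, edgeR adjusted p = 0.000107), which also stood higher in the mutant barcodes that failed the filters. Cwc22 rose there too, from 43.1 and 12.8 CPM, the second below the floor of 38.4 CPM, to 319 and 186 CPM (2.61, edgeR adjusted p = 0.000374), and Tmem14c fell from 88.9 and 89.5 CPM to 23.1 and 19.2 CPM (-2.13, edgeR adjusted p = 0.00837). In Purkinje-like cluster 10, Sncg, Prph and S100a10 rose by 5.78, 4.58 and 3.67 on the log2 scale. Each stood at 0 in control replicate 2, which held 21 cells there, so that 3 counts correspond to 51.8 CPM.

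Gdf10, a secreted factor of Bergmann glia, averaged 74.7 ± 5.81 CPM in control and 32.6 ± 2.75 CPM in mutant cells over all cells (SD, n = 2 libraries each). It passed edgeR when adjusted over the glia list alone (0.0176) and did not pass over all genes. Gdf10 does not stand for that list, of whose 13 members tested 10 were higher and 3 lower. Astroglia-like cells made up 8.47 ± 4.93% of control and 13.8 ± 1.91% of mutant cells (SD, n = 2, exact permutation p = 0.333, the smallest possible). The difference of 5.37 points turned to -7.59 with the stricter cell filter and to -7.07 in cells with at least 2000 UMIs. With doublets kept it was 4.89 and the shares of the genotypes overlapped (exact permutation p = 0.667).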
